A study of Mus musculus with 4 samples.

How the data were processed

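Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase cuts accessible DNA and inserts sequencing adapters, in epithelial nuclei from the lungs of male mouse embryos at embryonic day 12.5. The labels give 4 samples in 2 groups of 2, the genotypes CTRL (control) and CKO. CKO was read here as a knockout. The labels do not name the deleted gene, and the series title names CTCF, a DNA-binding protein that holds chromatin loops together.

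The deposited data consisted of 4 interval lists, a control peak list and a loss list attached to control replicate 1, and a knockout peak list and a gain list attached to knockout replicate 1. Each list held a chromosome, a start and an end for every interval and no peak height, fold change, p-value or read number. Build mm10 and the tools cutadapt 2.5, Bowtie2 2.3.4.3, Picard 2.20.7 and MACS2 2.2.4 are named per the submitters' processing notes. The peak threshold, any shift of the Tn5 cut positions, the filters, the pooling of replicates and the method behind the loss and gain lists were not given in the sources used here. The names loss and gain were taken to mean lower and higher accessibility in the knockout. As a check, every loss region lay in a control peak and every gain region in a knockout peak. A pooled or a single-replicate peak call would make different lists from the same reads, and a difference in depth or enrichment between the genotypes would change which peaks pass a threshold. Sequencing depth was unknown, since the lists hold no read numbers.

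Intervals were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. Intervals that shared at least 1 bp were counted as overlapping, each interval once. Shares carry 95% Wilson intervals, which cover counting error only. Peaks that overlapped neither a loss nor a gain region were called unchanged, which means only that they hold no region of either list.

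Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the assembly behind mm10, with 49943 genes. The table gives the start and end of each gene without its strand, so the planned promoter class was replaced by a gene-end class, a region that overlaps the 1 kb either side of either end of an annotated gene. For the same reason each region was assigned, by its midpoint, to the gene whose body it lay in or to the nearest gene within 50 kb, among 21889 protein-coding genes together with H19 and Meg3. A gain region and the peak that holds it can therefore fall to neighbouring genes. Of the genes in the lists below, 523 list entries matched the table and 0 did not. No genome sequence was used here, so the planned searches for the CTCF motif and for 28 motifs in all, and the GC content of the regions, were not run. The planned percentile of peak signal was replaced by the percentile of peak width, and alternatives that needed a signal or q-value were replaced by ones based on width.

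Gene-end shares of loss and gain regions were compared with those of unchanged peaks of the same genotype by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 2 tests. For 23 gene lists fixed before the data were examined, the number of genes with at least 1 loss or gain region was compared with 10000 random lists of the same size, matched on the number of merged control and knockout peaks per gene in bins of at least 50 genes. The two-sided permutation p-values were adjusted by Benjamini-Hochberg over 46 tests, and 0.0002 is the smallest p that these draws can give. Genes of the Hox and protocadherin clusters are neighbours, which the random lists were not. Clustering was the share of regions with another of the same list within 50 kb, compared with 1000 draws of as many peaks from the list they came from, for which the smallest two-sided p is 0.002. Regions, peaks and genes are not replicates: every test describes these lists, and with 1 list per genotype no difference between genotypes could be set against the spread between samples.

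The genes named were fixed before the data were examined: 18 loci of lung development and related processes, Ctcf among them, the 10 genes with the most loss and the 10 with the most gain regions, with ties broken by the share of the gene's peaks and then by symbol, and up to 6 members of any list that passed an adjusted p of 0.05. A planned choice by peak signal could not be made. Other members of the lists are named as examples and were chosen after their values were seen.

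The tests were run first on simulated data made from the real peaks and genes. A planted gene-end odds ratio of 3 came back as 3.02 for loss-sized and 2.98 for gain-sized sets, and with no effect 0 of 20 simulated sets of either size passed 0.05. For gene lists with no effect, 3 of 230 loss-type and 8 of 230 gain-type tests had p under 0.05. A list whose genes were drawn with a 4-fold weight had p under 0.05 in 18 of 20 loss-type and 20 of 20 gain-type runs. Planted clusters were found in 20 of 20 runs for each set. The simulated sets were whole peaks drawn without regard to width, so these runs do not cover an effect of peak width. Alternatives covered the overlap rule, the gene-end window, gene types, assignment distance, background peaks, clustering distance and the sex chromosomes.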

Results

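Accessible chromatin of lung epithelial nuclei at embryonic day 12.5, when the lung epithelium is branching, was compared between a control and a knockout genotype, each with 2 labelled samples. The interval lists are attached to replicate 1 of each genotype, and whether they also draw on replicate 2 was not given in the sources used here. The lists held 73160 control peaks that covered 40.7 Mb and 68613 knockout peaks that covered 41.9 Mb of the mm10 genome. A further 2383 regions were listed as lost and 11707 as gained in the knockout, nearly all of them 400 bp wide. Each genotype had 1 list, so no difference below has a replicate check, read depth was unknown, and intervals on shares cover counting error only. Nothing in the labels says whether the samples of a genotype came from separate embryos.

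The gene that the series title names, Ctcf, lay on chromosome 8 from 105636474 to 105682922. It had 1 assigned control peak and 2 assigned knockout peaks, with 0 loss and 0 gain regions. The deleted part of the gene was not given in the sources used here, so these peaks check nothing about the deletion.

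The comparison asked which regulatory regions opened or closed in the knockout epithelium. Gain regions outnumbered loss regions 4.91 to 1 (95% interval 4.70 to 5.13), and the regions of each kind differed in form. Loss regions were mostly sites without any knockout peak: 2114 of 2383 (88.7%, 87.4 to 89.9%) overlapped none, while 269 did. Gain regions were mostly sites already open in the control: 10219 of 11707 (87.3%, 86.7 to 87.9%) overlapped a control peak, and 1488 did not. The odds ratio between these shares was 54.0 (47.0 to 62.0), with a two-sided Fisher's exact p at 1e-300, the smallest value printed. Peak width was not held constant in this comparison. Gain regions lay mostly in wide peaks, and of the knockout peaks at or above the median width 92.1% overlapped a control peak.

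Most peaks were shared between the genotypes. Of the control peaks, 69.2% (68.9 to 69.5%) overlapped a knockout peak, and of the knockout peaks 73.6% (73.3 to 74.0%) overlapped a control peak. Control peaks without a knockout peak numbered 22537, and 9.37% of them held a loss region. Knockout peaks without a control peak numbered 18090, and 8.46% held a gain region. Counted by presence in only 1 genotype, the ratio of knockout to control peaks was 0.803, the opposite direction to the deposited lists.

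Of the loss regions, 47.6% lay inside genes, away from their ends, and 34.1% between genes, against 47.2% and 28.7% of unchanged control peaks. Nav2, which encodes a neuron navigator protein, had the most, with 5 loss regions, 4 of them within the gene on chromosome 7, beside 7 gain regions. Syn3, a synapsin gene, had 4 within its body on chromosome 10. Tmem121 had 4 outside its body, between 113217321 and 113223247 on chromosome 12, and its assigned peaks numbered 9 in the control and 4 in the knockout. A further 12 genes carried 3 each, of which the naming rule took the 7 with the largest share of their peaks: Dand5, which encodes a secreted Nodal antagonist, Tanc2, Plec, which encodes the cytoskeletal linker plectin, Tmem170b, Cpz, Mlip and Ece1, which encodes an endothelin-converting enzyme. Dand5 and Tmem121 had 0 gain regions. In all, 1989 of 21889 genes (9.1%) had at least 1 loss region.

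Regions at gene ends, a class that holds promoters and transcript ends alike, made up 18.3% of loss regions (435 of 2383, 16.8 to 19.9%) and 24.1% of unchanged control peaks. The odds ratio was 0.705 (0.634 to 0.783, two-sided Fisher's exact p = 2.41e-11, adjusted p = 2.41e-11). This depletion was not present with a window of 2500 bp (odds ratio 0.998, Fisher's exact p = 0.982) or among peaks of like width (0.942, 0.846 to 1.05, p = 0.270 by a Mantel-Haenszel test over 10 width groups).

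Gain regions fell at gene ends far more often. Of 11707, 5788 (49.4%, 48.5 to 50.3%) lay at a gene end, against 24.9% of unchanged knockout peaks, an odds ratio of 2.96 (2.84 to 3.08) with Fisher's exact p and adjusted p at 1e-300. Among gain regions inside a control peak, 54.6% lay at gene ends. Those that overlapped no control peak had 14% at gene ends, 49.7% further inside genes and 36.4% between genes, and the odds ratio between both kinds was 7.40 (6.36 to 8.61, Fisher's exact p = 4.51e-207). The loss list had the same direction, with 31.6% at gene ends for regions in a knockout peak and 16.6% for those without. Peak width was not held constant in either split. The excess of gain regions at gene ends over unchanged peaks was smaller among peaks of like width, with an odds ratio of 1.46 (1.39 to 1.53).

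**Figure D1:**
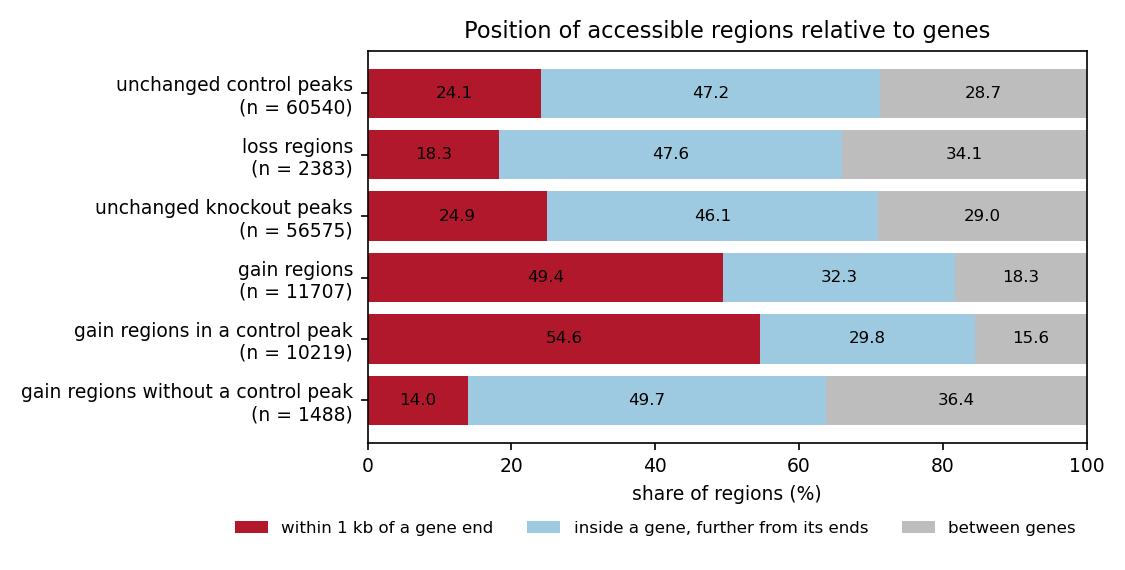
Share of regions (horizontal axis, percent) within 1 kb of a gene end, further inside a gene, or between genes, for 6 sets of regions with their numbers. Gain regions in a control peak lay at gene ends in 54.6% of cases and gain regions without one in 14%.

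Wide peaks carried most gain regions. Peaks that held a gain region had a median width of 853 bp, against 529 bp for all knockout peaks, and their median percentile in that list was 78.8. Peaks that held a loss region were narrow, with a median of 390 bp against 468 bp for all control peaks and a median percentile of 38.1. Among 47996 peaks that matched 1 to 1 between the genotypes, the share with a gain region was 7.90% in the narrowest of 5 groups of control width and 42.8% in the widest. Grouped by the geometric mean of both widths, a choice made after the data were examined, these shares were 4.48% and 44.4%. A loss region was present in 0.15%, 0.52%, 0.96%, 0.91% and 0.23% of the groups from narrowest to widest.

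**Figure D2:**
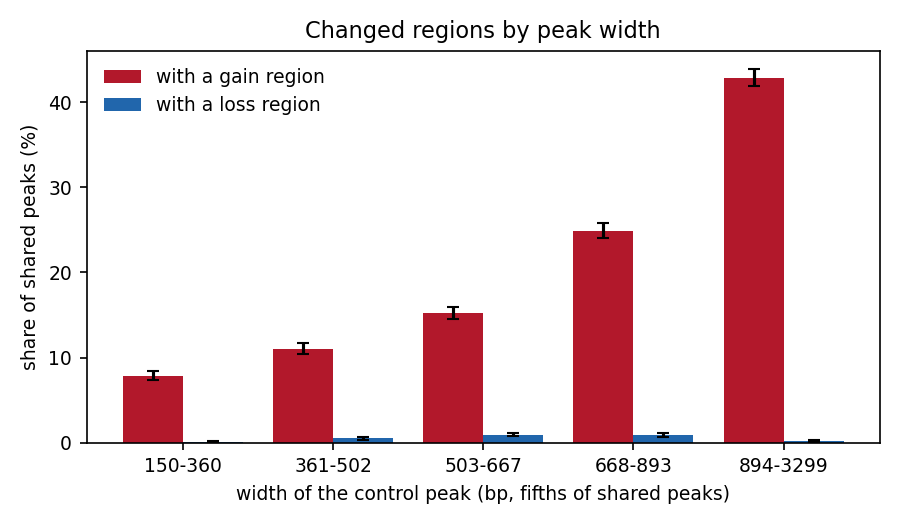
Share of peaks matched 1 to 1 between the genotypes (vertical axis, percent) that held a gain or a loss region, in 5 equal groups of control peak width (horizontal axis, bp); error bars are 95% Wilson intervals. The share with a gain region went from 7.90% to 42.8% across the groups.

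Counts of gain regions per gene, which were not corrected for gene length or number of peaks, were highest at Tead1 and Macrod2. Tead1, a transcription factor gene of the Hippo pathway, had 13 gain regions, 0 loss regions and 34 control and 31 knockout peaks. Macrod2, which encodes an ADP-ribose hydrolase, also had 13. Shroom3, whose product drives apical constriction of epithelial cells, and Tenm3, a teneurin gene, had 12 each. Arhgap23, Pawr, Celf4, Mob3b and Magi2, the last a scaffold gene of cell junctions, had 8 each and were taken by the naming rule from 8 genes with that count. Slc25a21, which encodes a mitochondrial carrier, had 9 gain regions, 5 of them without a control peak, and its peaks numbered 14 in the control and 24 in the knockout. Its body, from 56712634 to 57197472 on chromosome 12, lies between the lung transcription factor genes Nkx2-1 and Foxa1. At least 1 gain region was assigned to 7408 genes (33.8%), and 1042 of these also had a loss region.

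Target genes of p53, the transcription factor that responds to DNA damage and other stress, carried gain regions more often than matched genes. Of the 23 listed targets, 19 had a gain region, where random lists had a median of 9 (central 95% 5 to 14; permutation p = 0.0002, the smallest the draws can give; Benjamini-Hochberg adjusted p = 0.0092). It was the only one of the 23 lists to pass in either set, and 1 of its genes, Psrc1, had a loss region, against a random median of 2. Cdkn1a, which encodes a cyclin-dependent kinase inhibitor and is a classical p53 target, lay on chromosome 17 from 29090979 to 29100722. It had 4 control peaks, 9 knockout peaks and 7 gain regions, 5 of which overlapped no control peak. Of these 5, the region from 29090751 to 29091150 covered the start coordinate of the gene. A pair at 29078177 to 29078576 and 29078895 to 29079294 lay outside the gene, with midpoints 12602 and 11884 bp from its nearer end.

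**Figure D3:**
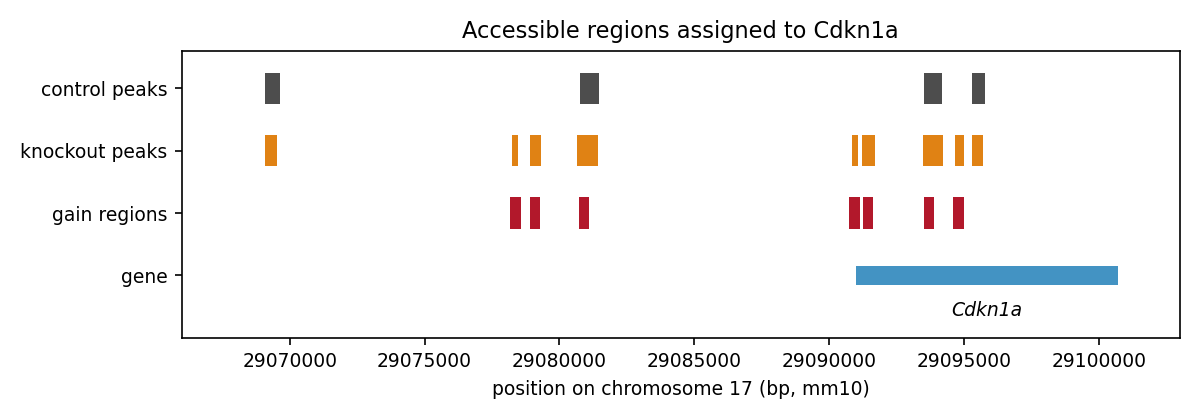
Control peaks, knockout peaks and gain regions assigned to Cdkn1a along chromosome 17 (horizontal axis, bp, mm10), with the extent of the gene. There were 4 control peaks, 9 knockout peaks and 7 gain regions.

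Perp, which encodes a membrane protein of desmosomes, and Btg2, an antiproliferative gene, had 3 gain regions each. Bax and Bbc3, which encode proteins that promote apoptosis, and Sesn2, a stress-induced sestrin gene, had 2 each. Those of Bax lay at 45460849 to 45461248 and 45466660 to 45467059 on chromosome 7, close to the ends of the gene. Of the remaining targets, Zmat3 and Plk2 had 2 gain regions and Ccng1, Eda2r, Polk, Tigar, Trp53inp1, Psrc1, Mdm2, Rrm2b, Aen, Fas and Pmaip1 had 1. Apaf1, Ei24, Phlda3 and Tnfrsf10b had 0. Trp53, the gene for p53 itself, had 1 gain region at a gene end. Counting only gain regions beyond 1 kb from any gene end left 8 targets against a random median of 4, with an adjusted permutation p of 0.630. Counting only those without a control peak left 4, Cdkn1a, Btg2, Zmat3 and Fas, against 1, with an adjusted permutation p of 0.619.

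Apoptosis genes had gain regions in 14 of 21 cases against a random median of 9 (permutation p = 0.0478, adjusted p = 0.354), a list that shared 5 genes with the p53 targets. Without those 5, the count was 10 of 16 against 7 (permutation p = 0.178). Cell cycle genes had 9 of 23 against 10. Ccnd1 had the most, with 3 gain regions beside 1 loss region. Ccne1 and Aurkb had 2 gain regions each, and E2f1, Mcm5 and Cdk4 were among those with 1.

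Genes that set lung identity had gain regions often, without passing the adjusted test. Among 22 lung endoderm transcription factors, 20 had a gain region against a random median of 15 (permutation p = 0.0344, adjusted p = 0.354). Foxa2, a pioneer factor gene, had 4, with 13 control and 21 knockout peaks. Foxa1 had 2, and Nkx2-1, the master regulator of lung fate, and Gata6 had 1 each, in control peaks. Shh, which encodes the ligand that signals from epithelium to mesenchyme, had 3 gain regions inside the gene on chromosome 5, 2 of them without a control peak, and 1 loss region from 28469703 to 28470102. When only regions at gene ends were counted, this list had 17 genes against 9 (adjusted permutation p = 0.023).

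Distal tip progenitor genes had a gain region in 13 of 15 cases against a random median of 10 (permutation p = 0.0802, adjusted p = 0.461), and 1 of 15 had a loss region. Bmp4 and Id2, a signal and a transcriptional inhibitor of the branching tips, had 5 gain regions each. Etv5, a transcription factor gene downstream of Fgf signalling, had 2, and Sox9 and the receptor gene Fgfr2 had 1. Sftpc, the surfactant protein C gene, had 0 peaks in either genotype. With regions at gene ends alone the count was 12 against 6 (adjusted permutation p = 0.0337). Proximal airway genes, by comparison, had 6 of 18 against a random median of 9 (permutation p = 0.300, adjusted p = 0.909). Sox2, the proximal regulator, had 8 control peaks, 6 knockout peaks and 0 gain regions, and Trp63, a basal cell regulator, had 1. Hes1 had the most of the proximal list, with 4, and Foxj1, Cftr and Rfx2 had 2 each. The difference between the distal and the proximal list was not tested.

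**Figure D4:**
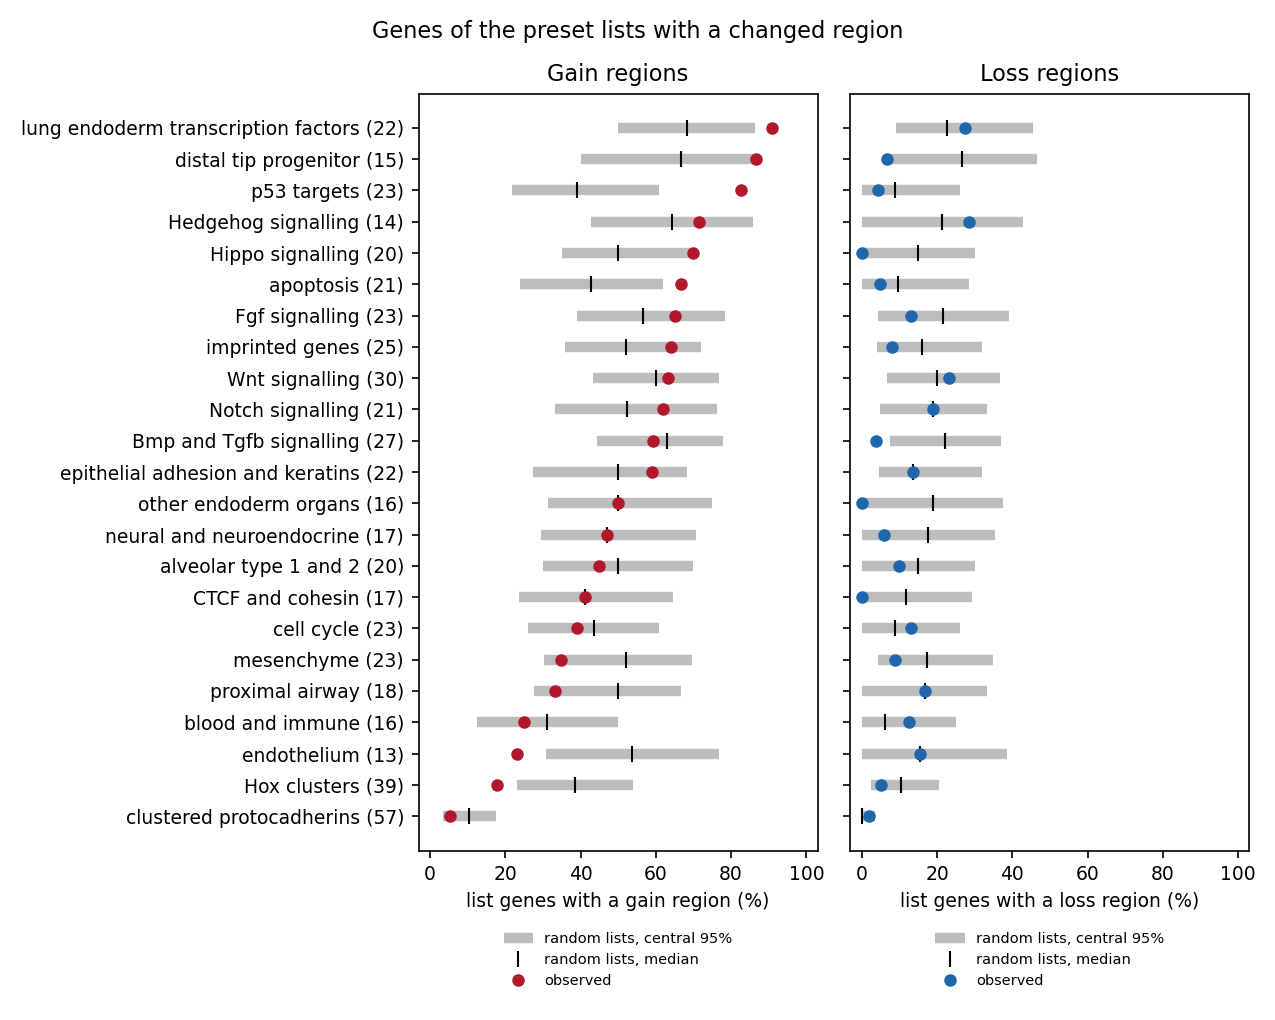
Share of the genes of each of 23 lists (number of genes in brackets) with a gain region or a loss region (horizontal axes, percent). Points are observed shares, bars the central 95% and ticks the median of 10000 matched random lists; the p53 targets stand at 82.6% against 39.1% for gain regions.

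Epithelial adhesion and keratin genes had gain regions in 13 of 22 cases against a random median of 11, among them the E-cadherin gene Cdh1 and the splicing regulator gene Esrp2 with 3 each. Alveolar genes had 9 of 20 against 10. Pdpn, a marker of flat alveolar cells, Clic5 and Vegfa had 3 gain regions each. Their control and knockout peaks numbered 5 and 11 for Pdpn, 16 and 16 for Clic5, and 17 and 13 for Vegfa.

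Markers of other cell types that such nuclei could hold did not pass the adjusted test. Endothelial genes had a gain region in 3 of 13 cases against a random median of 7 (permutation p = 0.0434, adjusted p = 0.354), and mesenchymal genes in 8 of 23 against 12. Blood and immune genes had 4 of 16 against 5, neural and neuroendocrine genes 8 of 17 against 8, and genes of other endoderm organs 8 of 16 against 8. For loss regions the same 5 lists had counts of 2, 2, 2, 1 and 0 against random medians of 2, 4, 1, 3 and 3.

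No list of signalling genes passed the adjusted test. Hippo genes had 14 of 20 against a random median of 10 (permutation p = 0.138), with 13 regions at Tead1 and 5 at Wwc1, and 0 of 20 had a loss region against 3. Wnt genes had 19 of 30 against 18, Fgf genes 15 of 23 against 13, Hedgehog genes 10 of 14 against 9 and Notch genes 13 of 21 against 11. Bmp and Tgfb genes had 16 of 27 against 17. Loss regions touched 1 of these 27, Smad6, against a random median of 6 (permutation p = 0.0202, adjusted p = 0.31). By the same test 0 of 23 lists passed for loss regions after adjustment, and this was the 1 list with an unadjusted p under 0.05.

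Gene groups studied for their regulation by CTCF passed no adjusted test. Imprinted genes had gain regions in 16 of 25 cases against a random median of 13. Among them were Igf2 with 2, in control peaks inside the gene, and H19 with 1, which lay 33144 bp outside the gene. Hox genes had 7 of 39 against 15 (permutation p = 0.0094, adjusted p = 0.216), and clustered protocadherin genes 3 of 57 against 6, where 17 of the 57 had any peak. Genes for CTCF and cohesin factors had 7 of 17 against 7, and 0 of 17 had a loss region.

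Changed regions lay closer together than randomly drawn peaks, which were not matched on width, position at gene ends or local peak density. Another loss region was found within 50 kb of 24.0% of loss regions, against 16.5% (central 95% 14.7 to 18.5%) in draws of control peaks (permutation p = 0.002, the smallest the draws can give). For gain regions the share was 58.6% against 54.7% (53.7 to 55.7%; permutation p = 0.002). At 200 kb the gain regions were no longer closer than drawn peaks, with a ratio of 0.9995 (permutation p = 0.893).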

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

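Alternatives based on peak width, midpoints of regions at gene ends, the nearest gene end, subsets of gain regions, matching the p53 list on control peaks alone, width percentiles without the sex chromosomes, and mean width of shared peaks were chosen after the data were examined. Of 54 alternative values, 38 kept their direction and their side of the threshold or stayed within the interval of the reported value. These values are not independent, since the p53 list counts both alone and among the gene lists for gain regions. The ratio by covered length was bound to stay close, as nearly all regions are 400 bp wide. The share of control peaks with a knockout peak was 62.43% at 50% reciprocal overlap, 67.53% by midpoints, 75.11% within the wider peaks of both lists and 89.23% for the wider control peaks against all knockout peaks. The knockout share was 66.56%, 71.27%, 79.72% and 92.12% in the same order. Rebuilt from peaks present in 1 genotype alone, the gain to loss ratio was 0.803. Those rebuilt lists are made mostly of other peaks, as 20425 of 22537 control and 16560 of 18090 knockout peaks in them hold no deposited region. The loss odds ratio at gene ends was 0.998 with a 2500 bp window, where the cause was not tested, and 0.942 within 10 width groups. Clustering of gain regions had a ratio of 0.9995 at 200 kb, and the cause was not tested. Counting regions at gene ends alone raised the lists that passed for gain from 1 to 3, by adding distal tip progenitor and lung endoderm transcription factor genes; the cause was not tested. The p53 count was 8 beyond gene ends and 4 without a control peak, both from fewer regions and no longer past the adjusted threshold. In the other 7 alternatives for that list it was 16 to 20, with adjusted permutation p from 0.0092 to 0.0276.

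No paired analysis was possible because the replicate numbers 1 and 2 occur in both genotypes but each genotype has 1 interval list. Leaving out a replicate could not be run for the same reason, and alternatives that need peak signal, q-values or DNA sequence were not run. Depth limits all calls to an unknown degree, since the lists hold no read numbers.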

Other observations

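Of the tests below, the test of power by the width of peaks with a loss region, the grouping by mean width, the subsets of gain regions used for the gene lists and the choice of the distal tip list were made after the results were seen.

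Gain regions that overlapped no control peak, new only in being absent from the control list, were assigned to more distal tip progenitor genes than to matched genes. Of the 15 listed genes, 8 had such a region against a random median of 2 (central 95% 0 to 5; permutation p = 0.0008, adjusted p = 0.0368 over the 46 tests of this subset alone). In the other subset, gain regions beyond gene ends, this list had 10 genes against 7 (adjusted permutation p = 0.868). The 8 genes with a new site were Bmp4, Wnt7b and Lin28a with 2 each and Id2, Fgfr2, Lin28b, Dusp6 and Hmga2 with 1 each. Some lay far from the gene: those of Bmp4 were 28896 and 49265 bp outside it and that of Dusp6 30147 bp. That of Id2 was 4150 bp outside, and those of Fgfr2, Lin28b and Hmga2 lay inside the gene. Wnt7b, an epithelial Wnt ligand gene, also carried 3 loss regions, the only ones in this list, at 85583052 to 85583451, 85598824 to 85599223 and 85610610 to 85611009 on chromosome 15. Its new gain regions lay inside the gene at 85577739 to 85578138 and 85580390 to 85580789. Lin28a and Lin28b encode RNA-binding proteins of early progenitors, and Dusp6 is a feedback inhibitor gene of Fgf signalling. A hypothesis is that new accessible sites in the knockout may collect around genes of the tip program. With random lists matched also on the widest control peak, the median was 3 (0 to 6) and the permutation p 0.0024, adjusted to 0.11 over 46 tests. The bound set for this test had been an unadjusted p of 0.05, which is laxer than the threshold behind the call, so larger peaks near these genes stay open as an explanation.

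Loss and gain regions were neighbours more often than unchanged control peaks and gain regions were. Within 50 kb, 60.6% of loss regions had a gain region, against 49.6% (47.7 to 51.5%) of drawn unchanged control peaks (permutation p = 0.002, the smallest the draws can give). With draws matched on the number of merged peaks within 50 kb, the share was 55.0% (53.2 to 56.9%), so the number of nearby peaks could account for part of the difference and not for all of it. The width of the nearby peaks and their position at gene ends were not matched and stay open. Whether sites within such neighbourhoods exchange accessibility is a hypothesis that these lists cannot test.

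Gain regions outnumbered loss regions and mostly lay in peaks of both genotypes. Test power alone would favour wide peaks in both directions. Control peaks with a loss region lay at a median width percentile of 38.1 (95% bootstrap interval 36.8 to 39.6). Knockout peaks with a gain region lay at 78.8 (78.3 to 79.3). These percentiles cannot decide on test power, since 2112 of the 2385 control peaks with a loss region had no knockout peak. Peaks without a partner were mostly narrow: of the control peaks at or above the median width, 89.2% overlapped a knockout peak. Among shared peaks, the loss share was 0.15% in the narrowest, 0.96% in the middle and 0.23% in the widest of 5 groups. Peak size was related to the gain calls, with a gain region 5.43 times as frequent in the widest as in the narrowest of 5 groups of shared peaks by control width and 9.92 times by mean width. Higher enrichment of the knockout libraries and a broad opening of promoters in the knockout cannot be told apart: shared peaks with neither kind of region were slightly wider in the knockout (median log2 ratio 0.074, 0.071 to 0.078), those with a gain region hardly more so (0.091, 0.087 to 0.097) and those with a loss region narrower (-0.484, -0.569 to -0.412), and no read numbers were at hand to separate them. A biological effect of the genotype therefore stays open.

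The p53 targets passed the adjusted test in the gain list. Larger peaks near these genes were argued against by matching on the widest control peak, which left a permutation p of 0.0002. A general gain at gene ends stays open. Counted at gene ends alone, 16 targets had a gain region against a random median of 8 (adjusted permutation p = 0.0092). That count was not matched on the width of the peaks at gene ends. Among shared peaks at gene ends, 11.1% held a gain region in the narrowest and 47.6% in the widest of 5 groups of control width. In the same permutation test, distal tip progenitor genes (12 against 6, adjusted permutation p = 0.0337) and lung endoderm transcription factors (17 against 9, adjusted permutation p = 0.023) also passed. The count beyond gene ends did not pass adjustment (permutation p = 0.0274, adjusted p = 0.630). Whether new sites lay near these genes stays open, as that count did not pass adjustment either (permutation p = 0.0408, adjusted p = 0.619), and a candidate explanation of the excess is an active p53 response in the knockout epithelium, a hypothesis found and tested on the same lists, for which RNA levels were not analysed here.

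The X chromosome carried few changed regions. Of its knockout peaks 9.81% (8.41 to 11.4%) held a gain region, against 17.3% on the autosomes (odds ratio 0.520, Fisher's exact p = 4.83e-16), and of its control peaks 1.08% against 3.31% held a loss region (odds ratio 0.318, p = 2.47e-08 by the same exact test). For gain regions, narrow peaks were argued against. Knockout peaks on the X were wider (median 576 against 528 bp), and 19.2% (17.4 to 21.0%) of width-matched autosomal knockout peaks held a gain region. Control peaks with a loss region were not matched on width. They were narrow in the whole list (median 390 against 468 bp), so peak width stays open for the loss regions. The single X of male embryos, which would give fewer reads per site and could lower the power of a count test, stays open. No biological explanation was tested for this pattern.

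The deposited order of the lists went with overlap. With each list divided into 10 equal parts, 20.1% of loss regions in the first part and 6.3% in the last overlapped a knockout peak. For gain regions and control peaks the shares were 90.3% and 82.5%.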
